A study of Mus musculus with 199 samples.

How the data were processed

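The series holds 199 libraries of mouse RNA. Per the labels, whole liver tissue and tumours were sequenced from stranded mRNA libraries, and sorted Ly6G-positive neutrophils and CD3-positive T cells from stranded total RNA libraries for low input. The titles call the second source of the sorted cells liver, while the protocol in the labels names tumours as well as blood. Below, liver is used as in the titles. The authors deposited raw read counts per gene for all libraries in 1 table of 37713 Ensembl genes. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.4, HISAT2 2.1.0, HTSeq 0.11.2 and the genome build GRCm38. Settings such as the strand used for counting and the annotation release were not given in the sources used here, so overlapping genes on opposite strands and near-identical family members are uncertain. HTSeq keeps uniquely aligned reads, which lowers counts of genes with close copies.

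The table's 5 HTSeq summary entries held 63.2% of all entries and were left out of library sizes and tests. Of the genes 37607 were matched to a symbol by Ensembl identifier, and the 106 others held 0.00741% of gene counts. Entries that aligned to more than 1 place made up a median of 49.6% in whole tissue, 11.3% in neutrophils and 14.4% in T cells. Unaligned entries were 0% in whole tissue and 21.1% in neutrophils, so tissue and sorted cells were counted from differently made input and were never tested against each other. A median of 14851, 17587 and 18457 genes had a count in neutrophils, T cells and tissue. A count of 0 allows up to 3 counts of a library's total. Counting error was not compared with the spread between libraries, and levels well under 1 CPM rest on few counts.

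Groups came from the titles and treatment labels. Untreated DEN ALIOS libraries include some labelled Vehicle, and CXCR2i libraries some labelled as aPD1 isotype, and both were left out in an alternative. Sequencing runs in the labels were joined into run sets A to F for sorted cells, and tissue had 3 runs. Whole-tissue libraries carry no animal, so their p-values measure the spread between samples, some of which may share a mouse. Liver and blood libraries of sorted cells name the animal, which ties 29 neutrophil and 22 T cell sets of liver and blood. Deviations from the group means correlated by 0.067 within and -0.024 between animals for neutrophils and by 0.175 and -0.062 for T cells. Liver against blood was fitted with the animal as a block. Among 1116 library pairs within groups the lowest chi-square per degree of freedom was 2.57, so none was a copy within sampling noise.

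Tests used edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. All treatment groups of a cell type and site shared a fit with run set as a term, tissue fits had the run as a term, and fits against PBS had none because run and group coincide. Standard errors were derived from the fold change and the F statistic. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 on log2 CPM (prior count 2.00) with a preset correlation of 0.01 and, as an alternative, an estimated one. Alternatives were DESeq2 1.42.0, RLE factors, no filter, a 2-fold minimum, no run term, single runs, single run sets, the title number as a replicate block, left-out labels and, for sorted cells, each replicate left out. Figures were drawn with matplotlib 3.10.9.

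Named genes followed a rule fixed before the data were examined. It took *Cxcr2*, *Cxcr1*, *Pdcd1*, *Cd274*, *Cxcl1*, *Cxcl2* and *Cxcl5* where tested, and up to 3 called members of each list with the largest change, or 2 with the smallest p where none was called. It added the 6 largest rises and falls among called genes with a mean of at least 10 CPM in the higher group, leaving out predicted genes, immunoglobulin and T cell receptor segments, ribosomal and mitochondrially encoded genes and pseudogenes. The same genes were looked up in the cell type's other comparisons and are printed in part. On simulated counts with 200 changed genes the edgeR step recovered 93% of 2-fold and 99% of 4-fold changes in the design of large tumours against liver tissue, with 4.5% false calls.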

Results

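Expression was measured by RNA sequencing in a mouse model of hepatocellular carcinoma on a background of non-alcoholic steatohepatitis. In this model, called DEN ALIOS in the labels, mice receive the liver carcinogen diethylnitrosamine and a diet rich in fat and sugar. The 199 libraries fell into 23 groups. Whole tissue gave 65 libraries, 15 of liver tissue, 25 of small tumours and 25 of large tumours. Cells sorted from liver and blood gave 61 libraries of Ly6G-positive neutrophils and 73 of CD3-positive T cells. DEN ALIOS mice were untreated, or received an antibody to the T cell checkpoint receptor PD-1 (aPD1), an inhibitor of the neutrophil chemokine receptor CXCR2 (CXCR2i), or both. The liver neutrophil groups held 6, 5, 10 and 8 libraries in that order, and the blood neutrophil groups 7, 5, 10 and 10. The liver T cell groups held 6, 5, 6 and 5, and the blood T cell groups 7, 5, 6 and 5. A further 8 liver and 8 blood T cell libraries were labelled PBS and 6 of each CXCR2i, with no DEN ALIOS in the title.

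Gene counts per library ran from 12055434 to 21850190 in whole tissue (median 15178619), from 580113 to 9256224 in neutrophils (median 5690277) and from 337110 to 10755816 in T cells (median 6291781). Below, fold changes are log2 values ± standard error from edgeR quasi-likelihood fits, and CPM beside them are means ± SD per 1000000 counts after TMM scaling. Other CPM are per 1000000 gene counts of a library. A gene rose or fell when its Benjamini-Hochberg adjusted p was under 0.05. Untreated DEN ALIOS cells all came from run set A and most treated ones from others, so run set was a term of those fits. Fitted fold changes can therefore differ from ratios of group means.

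Large tumours were compared with liver tissue. Tumours held fetal and carcinoma-associated transcripts that were scarce in liver tissue. *Afp* (4.75 ± 0.55, from 10.8 ± 10.9 to 338 ± 511 CPM), which encodes alpha-fetoprotein and lies on chromosome 5 from 90490737 to 90508907 of GRCm38, and the oncofetal proteoglycan gene *Gpc3* (4.93 ± 0.56, from 15.9 ± 26.4 to 532 ± 427 CPM) both rose (n = 25 and 15). The intestinal cadherin gene *Cdh17* (6.17 ± 0.64) and the trypsin inhibitor gene *Spink1* (5.24 ± 0.50) also rose. Of the oncofetal and carcinoma markers 12 of 13 rose (12 adjusted over the list alone), among them the Golgi protein gene *Golm1* (3.65 ± 0.24) (camera adjusted p = 0.000253, adjusted p = 0.344 with an estimated correlation). Cell cycle genes rose in 26 of 30 cases (26 adjusted over the list alone), and fell in 1, with *Hmmr* (2.63 ± 0.30), *Ccne1* (2.50 ± 0.26) and *Cdc20* (2.35 ± 0.28) leading (camera adjusted p = 1.25e-06, adjusted p = 0.344 with an estimated correlation). Cholesterol synthesis rose in 19 of 20 genes (19 adjusted over the list alone), with *Sqle* (2.50 ± 0.20), *Lss* (1.85 ± 0.17) and *Dhcr7* (1.71 ± 0.13) (camera adjusted p = 1.86e-06, adjusted p = 0.344 with an estimated correlation). Matrix and stellate cell genes rose in 18 of 24 (18 adjusted over the list alone) and fell in 2, including the smooth muscle actin gene *Acta2* (2.12 ± 0.27), the collagenase gene *Mmp13* (1.98 ± 0.35) and *Timp1* (1.97 ± 0.32) (camera adjusted p = 0.00163, adjusted p = 0.663 with an estimated correlation).

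Many genes of the differentiated hepatocyte were lower in large tumours. *Cyp7a1* (-5.05 ± 0.72, from 336 ± 226 to 26.1 ± 69.4 CPM), the rate-limiting enzyme of bile acid synthesis, on chromosome 4 from 6265612 to 6275633, fell together with *Cyp8b1* (-3.89 ± 0.51) and the transporter gene *Slco1a1* (-4.10 ± 0.55). All 14 measured bile acid genes fell (14 adjusted over the list alone, camera adjusted p = 3.22e-07, adjusted p = 0.344 with an estimated correlation). Pericentral genes fell in 13 of 16 cases (13 adjusted over the list alone), with the alcohol-metabolizing cytochrome gene *Cyp2e1* (-4.31 ± 0.68), *Oat* (-3.75 ± 0.70) and the glutamate transporter gene *Slc1a2* (-4.00 ± 0.81) (camera adjusted p = 0.000193, adjusted p = 0.548 with an estimated correlation). Periportal genes fell in 12 of 14 (13 adjusted over the list alone), with *Cyp2f2* (-3.33 ± 0.41), the gluconeogenic gene *Pck1* (-2.21 ± 0.21) and the urea cycle gene *Ass1* (-1.98 ± 0.19) (camera adjusted p = 0.000557, adjusted p = 0.344 with an estimated correlation). Fatty acid oxidation genes fell in 13 of 17 (13 adjusted over the list alone), led by *Cyp4a14* (-5.46 ± 0.71) and *Cyp4a10* (-4.64 ± 0.49) (camera adjusted p = 2.38e-05, adjusted p = 0.344 with an estimated correlation). The secreted protein genes *Alb* and *Apoa1*, named after their values were seen, stood at 143200 ± 23420 and 19820 ± 3335 CPM in large tumours and at 59970 ± 16050 and 7559 ± 1791 in liver tissue.

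In the same comparison resident macrophage transcripts fell in all 11 measured Kupffer cell markers, and in 11 adjusted over the list alone (camera adjusted p = 2.33e-05, adjusted p = 0.344 with an estimated correlation). The scavenger receptor gene *Marco* (-4.87 ± 0.49, from 37.4 ± 25.5 to 1.39 ± 1.91 CPM), on chromosome 1 from 120474538 to 120505024, the phosphatidylserine receptor gene *Timd4* (-3.66 ± 0.37) and the lectin gene *Clec4f* (-2.50 ± 0.28) led these. T cell markers rose in 11 of 15 cases (11 adjusted over the list alone), including *Cd5* (1.17 ± 0.34) and *Cd8a* (1.11 ± 0.35), although the list as a whole did not pass (camera adjusted p = 0.322). *Pdcd1*, which encodes PD-1, rose by 1.87 ± 0.49 (adjusted p = 0.000633), while *Cd274*, which encodes its ligand PD-L1, had a fold change of -0.045 ± 0.15 (adjusted p = 0.804). Antigen presentation genes rose in 11 of 16 (11 adjusted over the list alone), with *Ciita* (0.96 ± 0.24) and *H2-Eb1* (0.95 ± 0.23). The neutrophil chemokine genes *Cxcl1* (2.46 ± 0.23) and *Cxcl2* (1.45 ± 0.30) rose. Of 7 neutrophil markers 1 fell, *Ngp* (-1.505 ± 0.64), which stood at -0.35 without the 4 tissue libraries over 10 CPM of the neutrophil gene *S100a8*, left out after seeing the data, where 1 marker, *Mmp9*, fell and 1, *Ltf*, rose. B cell markers moved both ways, with 5 of 8 falling and *Cr2* (1.02 ± 0.45) rising (adjusted p = 0.0502 without those libraries). In all, 10253 of 14538 tested genes changed, 5591 upward and 4662 downward, and 2587 of these by at least 2-fold.

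Small tumours, compared with the same liver tissue, also held fetal transcripts at high levels: *Afp* (4.27 ± 0.52, from 10.8 ± 10.9 to 226 ± 212 CPM), *Gpc3* (5.12 ± 0.56, from 15.9 ± 26.4 to 525 ± 309 CPM), *Cdh17* (5.61 ± 0.63) and *Spink1* (5.40 ± 0.50) rose (n = 25 and 15). Oncofetal markers rose in 11 of 13 (11 adjusted over the list alone, camera adjusted p = 0.000142, adjusted p = 0.334 with an estimated correlation). Cell cycle genes rose in 27 of 30 (27 adjusted over the list alone, camera adjusted p = 1.94e-07, adjusted p = 0.495 with an estimated correlation) and cholesterol synthesis genes in 19 of 20 (19 adjusted over the list alone, camera adjusted p = 1.94e-07, adjusted p = 0.495 with an estimated correlation), with *Ccne1* (2.80 ± 0.26) and *Sqle* (2.65 ± 0.20) as examples. *Cyp7a1* (-3.19 ± 0.67, from 336 ± 226 to 57.9 ± 64.6 CPM) and *Cyp2e1* (-3.06 ± 0.61) fell. Bile acid genes fell in 14 of 14 (14 adjusted over the list alone, camera adjusted p = 1.54e-06, adjusted p = 0.495 with an estimated correlation) and pericentral genes in 15 of 16 (15 adjusted over the list alone, camera adjusted p = 0.000542, adjusted p = 0.624 with an estimated correlation). Kupffer cell markers fell in 11 of 11 (11 adjusted over the list alone, camera adjusted p = 0.00178, adjusted p = 0.61 with an estimated correlation), with *Marco* (-2.99 ± 0.45, from 37.4 ± 25.5 to 5.06 ± 5.23 CPM) and *Timd4* (-2.27 ± 0.35). Neutrophil markers fell in 5 of 7 (6 adjusted over the list alone), among them *Ngp* (-1.80 ± 0.57), *S100a9* (-1.19 ± 0.31) and *Mmp9* (-1.14 ± 0.31), while the list did not pass (camera adjusted p = 0.273) and *Cxcl1* (2.09 ± 0.23) rose. Liver tissue replicates 4, 5 and 6 of the first run held *S100a8* at 18.4 to 21.6 CPM against 1.4 to 4.48 in the other 12, and without the libraries over 10 CPM 1 of 7 markers fell, *Mmp9* at -0.65, with *Ngp* at -0.12 and *S100a9* at -0.23. No T cell marker passed, and *Pdcd1* stood at 1.02 ± 0.49 (adjusted p = 0.0632) and *Cd274* at -0.13 ± 0.15 (adjusted p = 0.476). In all, 9558 genes changed, 5050 upward and 4508 downward.

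**Figure D1:**
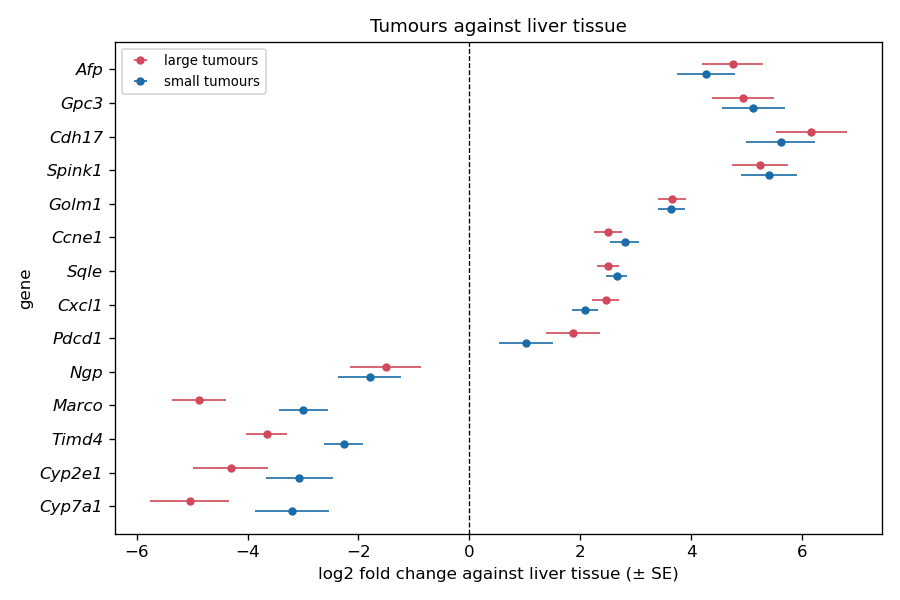
Log2 fold changes against liver tissue (n = 15) of 14 genes in large (n = 25) and small (n = 25) tumours. Points are edgeR estimates and bars are standard errors, and the dashed line marks no change. *Afp* lay at 4.75 and 4.27 and *Cyp7a1* at -5.05 and -3.19 in large and small tumours.

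Large and small tumours were compared. Kupffer cell genes were lower still in large tumours. *Marco* (-1.88 ± 0.45, from 5.06 ± 5.23 to 1.39 ± 1.91 CPM), *Timd4* (-1.39 ± 0.34) and the folate receptor gene *Folr2* (-1.12 ± 0.23) fell, as did 7 of 11 members of that list (8 adjusted over the list alone, camera adjusted p = 8.02e-13, adjusted p = 0.12 with an estimated correlation). Sinusoidal endothelial genes fell in 3 of 10 cases (5 adjusted over the list alone, camera adjusted p = 4.4e-05, adjusted p = 0.296 with an estimated correlation), namely *Clec4g* (-0.81 ± 0.18), *Dnase1l3* (-0.66 ± 0.14) and *Stab2* (-0.44 ± 0.11), whereas *Cd34* (0.81 ± 0.22) and the plasminogen activator gene *Plat* (1.08 ± 0.28) rose. *Slco1a1* (-2.13 ± 0.48) and *Elovl3* (-2.12 ± 0.52), hepatocyte genes with higher levels in male mice, and the PPAR alpha target gene *Cyp4a14* (-2.30 ± 0.60) fell. Of bile acid genes 1 fell over all genes and 8 of 14 when adjusted over the list alone (camera adjusted p = 2.2e-07, adjusted p = 0.296 with an estimated correlation). Of periportal genes 2 fell, *Arg1* (-0.39 ± 0.11) and *Uroc1* (-0.39 ± 0.11), and 8 of 14 did when adjusted over the list alone (camera adjusted p = 2.48e-06, adjusted p = 0.269 with an estimated correlation). *Pdcd1* did not pass (0.85 ± 0.38, adjusted p = 0.209). In all 360 genes changed, 135 upward and 225 downward (n = 25 and 25). The count was 565 by DESeq2 and 15, 75 or 157 when each of the 3 tissue runs was left out in turn, and 200 without the libraries over 10 CPM of *S100a8*, where *Cd34*, *Arg1* and *Uroc1* no longer passed.

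Liver and blood neutrophils of the same untreated DEN ALIOS animals were compared. Liver neutrophils held far more transcripts of inflammatory chemokines and cytokines. *Cxcl2* (8.90 ± 1.32, from 8.75 ± 6.78 to 5054 ± 3775 CPM), *Il1a* (10.19 ± 0.59) and *Cxcl3* (12.02 ± 0.85) rose, as did 18 of 19 genes of the inflammatory list (18 adjusted over the list alone, camera adjusted p = 9.46e-12, adjusted p = 0.29 with an estimated correlation). Immediate early genes such as *Egr1* (5.32 ± 0.86), *Fosb* (4.55 ± 0.59) and *Atf3* (3.49 ± 0.53) rose in 11 of 15 cases (12 adjusted over the list alone, camera adjusted p = 3.35e-06, adjusted p = 0.29 with an estimated correlation). The PD-L1 gene rose as well, *Cd274* by 2.09 ± 0.42. The chemokine receptor genes *Cxcr2* (-1.66 ± 0.42, from 2752 ± 563 to 1004 ± 483 CPM) and *Cxcr1* (-1.40 ± 0.50) fell, with 10 of 16 chemoattractant and adhesion receptors (10 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.47 with an estimated correlation). Tumour-associated neutrophil genes rose in 8 of 14 (9 adjusted over the list alone), among them *Spp1* (4.46 ± 0.62) and *Arg1* (4.45 ± 1.24) (camera adjusted p = 0.0222, adjusted p = 0.439 with an estimated correlation). The specific granule genes went both ways, with 7 rising, *Ltf* (2.75 ± 0.69) included, and 4 falling of 15.

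Markers of other liver cells rose with them. Hepatocyte markers rose in 13 of 13 cases (13 adjusted over the list alone, camera adjusted p = 9.07e-08, adjusted p = 0.29 with an estimated correlation), endothelial markers in 8 of 8 (8 adjusted over the list alone, camera adjusted p = 3.36e-05, adjusted p = 0.389 with an estimated correlation) and T and NK cell markers in 13 of 14 (13 adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.47 with an estimated correlation). Examples are *Apoa1* (6.71 ± 0.90), *Cdh5* (7.85 ± 1.23) and *Cd3e* (8.43 ± 1.87). Liver *Cd3e* was 47.4 and 57.4 CPM in replicates 2 and 5 and at most 1.16 otherwise. The complement gene *C1qa* of tissue macrophages was at 24.4 ± 26.1 CPM in liver and had no count in the blood libraries. The platelet genes *Ppbp* (-5.09 ± 0.74) and *Gp9* (-6.34 ± 1.07) fell. The chemokine rises above stand beside these rises of genes of cells a Ly6G sort should exclude. In all 5545 of 12831 genes changed (n = 6 and 6), 3356 upward and 2189 downward, with a median fold change of 0.148 over all genes. With RLE in place of TMM scaling the split was 3807 to 1631. Without shallow or mixed libraries, those with under 1000000 gene counts or over 20 CPM of the T cell gene *Cd3e*, 3449 genes changed. That rule was chosen after the data were seen.

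CXCR2 inhibition with aPD1, the combination, was compared with no treatment. Liver neutrophils of the combination group held many more transcripts of the secondary, or specific, granules, which neutrophils make while they mature in the bone marrow. *Ltf* (4.79 ± 0.88, from 424 ± 481 to 11020 ± 4370 CPM), the lactoferrin gene on chromosome 9 from 111019271 to 111042767, *Camp* (5.04 ± 0.92, from 35.9 ± 44.2 to 1035 ± 419 CPM), the cathelicidin gene on chromosome 9 from 109847379 to 109849617, *Ngp* (4.57 ± 0.85) and *Fcnb* (4.58 ± 0.78) rose (n = 8 and 6). In total 14 of 15 specific granule genes rose (15 adjusted over the list alone, camera adjusted p = 2.36e-19, adjusted p = 0.112 with an estimated correlation), and so did *Cebpe* (3.72 ± 0.57), which encodes a transcription factor of that stage. Cell cycle genes rose in 11 of 29 cases (17 rose and 1 fell adjusted over the list alone), with *Mki67* (2.58 ± 0.65), *Hmmr* (2.80 ± 0.74) and *Kif11* (2.65 ± 0.76) (camera adjusted p = 7.82e-09, adjusted p = 0.361 with an estimated correlation). The oxidase genes *Cybb* (3.06 ± 0.53) and *Cyba* (1.03 ± 0.29) and the nitric oxide synthase gene *Nos2* (3.52 ± 1.06) rose. The inflammatory list fell in 9 of 19 (14 adjusted over the list alone), among them *Cxcl3* (-5.92 ± 1.37), *Il1a* (-3.91 ± 0.88) and *Ccl3* (-3.07 ± 0.81) (camera adjusted p = 1.13e-06, adjusted p = 0.361 with an estimated correlation). Interferon-stimulated genes fell in 3 of 21 (5 adjusted over the list alone), namely *Isg15* (-1.57 ± 0.43), *Ifit2* (-1.53 ± 0.36) and *Rsad2* (-1.89 ± 0.43) (camera adjusted p = 0.000719, adjusted p = 0.361 with an estimated correlation). *Spp1* (-3.69 ± 0.76), which encodes osteopontin, fell too. *Cxcr2* itself stood at -0.21 ± 0.55 (adjusted p = 0.846) and *Cd274* at -1.69 ± 0.61 (adjusted p = 0.0727).

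Lymphocyte transcripts were lower in the same comparison. B cell markers, with a median of -4.78 that was -2.34 without the shallow or mixed libraries and -2.29 within run set A, fell in 8 of 9 cases (9 adjusted over the list alone, camera adjusted p = 1.88e-05, adjusted p = 0.361 with an estimated correlation). The complement receptor gene *Cr2* (-6.45 ± 1.24, from 13.8 ± 21.4 to 0.266 ± 0.403 CPM), on chromosome 1 from 195136811 to 195176716, and *Fcer2a* (-6.86 ± 1.35) fell, as did *Gzmb* (-6.67 ± 1.80) and *Il7r* (-6.25 ± 1.34). Endothelial markers fell in 2 of 8 (5 adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.361 with an estimated correlation), *Kdr* (-2.98 ± 0.84) and *Cdh5* (-2.61 ± 0.76). Over all genes, 676 were higher and 612 lower of 11945, with a median fold change of -0.132. The split became 614 to 798 with RLE scaling and 835 to 1341 by DESeq2. Within run set A, which held 5 treated and all untreated libraries, 307 genes changed and *Ltf* stood at 4.87. Without the shallow or mixed libraries 2176 genes changed, 960 of them among the 1288. Without CXCR2i and aPD1 replicates 3 and 4 in turn the count was 759 and 827.

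**Figure D2:**
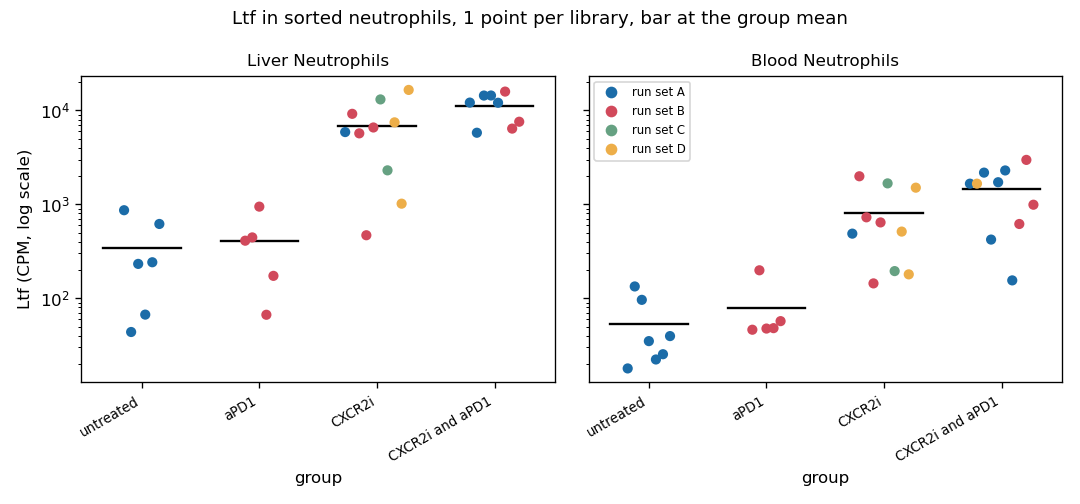
*Ltf* CPM per library (of gene counts, log axis) in neutrophils of liver and blood by treatment, with colour for the run set and a bar at the group mean. In liver the libraries ran from 43.7 to 865 CPM untreated and from 5783 to 15860.0 CPM with CXCR2i and aPD1, and in blood from 17.9 to 134 and from 155 to 2972 CPM.

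CXCR2 inhibition without aPD1 moved single liver neutrophil genes in 17 cases, 13 upward and 4 downward (n = 10 and 6). The receptor gene *Acvrl1* (4.04 ± 0.63), the stem cell antigen gene *Prom1* (3.43 ± 0.72) and the protease inhibitor gene *Serpinb1a* (3.22 ± 0.67) rose, and *Ifit2* (-2.47 ± 0.46) fell. Specific granule genes rose in 1 case over all genes and in 12 of 15 adjusted over the list alone (camera adjusted p = 2.02e-17, adjusted p = 0.162 with an estimated correlation). Interferon-stimulated genes fell in 1 and 11 of 21 cases by the same measures (camera adjusted p = 5.63e-09, adjusted p = 0.253 with an estimated correlation). Hepatocyte and B cell markers had medians of -3.05 and -3.55, with 9 and 9 members falling when adjusted over the list alone. The count was 326 by DESeq2, 645 without the run term and 1 without the libraries labelled Vehicle or isotype. Without untreated replicates 1, 3 and 5 in turn the count was 91, 6 and 1. It was 0, 7, 31, 11 and 27 without CXCR2i replicates 1, 2, 4, 5 and 9 in turn.

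With aPD1 alone no liver neutrophil gene passed by edgeR (n = 5 and 6), where 676 of 11945 had an unadjusted p under 0.05, and the count by DESeq2 was also 0. Cell cycle genes had a median of 1.499 (camera adjusted p = 6.26e-11, adjusted p = 0.502 with an estimated correlation) and inflammatory genes one of -1.46 (camera adjusted p = 4.49e-07, adjusted p = 0.593 with an estimated correlation), with no member passing in either. *Mki67* was at 232 and 324 CPM in aPD1 replicates 2 and 4 and from 36.0 to 45.6 in the others, and these 2 libraries held *Cd3e* at 94.3 and 236 and *Alb* at 1981 and 1840 CPM. Without the shallow or mixed libraries, these among them, the medians were 1.57 and -1.27. No untreated library shared a run set with an aPD1 library, so this comparison is linked through the combination and CXCR2i groups, and without the run term 38 genes passed.

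Against aPD1 alone, the combination raised the granule genes again. *Ltf* (4.77 ± 0.98), *Camp* (4.65 ± 1.01), *Ngp* (4.63 ± 0.96) and *Serpinb1a* (3.95 ± 0.66) rose, with 5 of 15 list members (15 adjusted over the list alone, camera adjusted p = 4.26e-25, and 0.0399 with an estimated correlation). T and NK cell markers had a median of -4.52, with 9 of 10 falling when adjusted over the list alone and 0 over all genes. In all 53 genes rose and 0 fell (n = 8 and 5). The count was 2 within run set B, 24 with RLE scaling, 129 up and 24 down by DESeq2, and 0 without the shallow or mixed libraries. Without CXCR2i and aPD1 replicates 1 to 8 in turn the count was 20, 34, 33, 24, 28, 0, 21 and 18. It was 0, 0, 0 and 17 without aPD1 replicates 1, 2, 4 and 5 in turn.

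Against CXCR2i alone, no gene of the combination group passed by edgeR (n = 8 and 10), 488 had an unadjusted p under 0.05, and 1 passed by DESeq2. *Camp* stood at 1.48 ± 0.85 (adjusted p = 0.917) and *Cebpe* at 1.53 ± 0.55, neither passing.

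In blood, the combination also raised specific granule genes in neutrophils. *Ltf* (4.50 ± 0.74, from 56.6 ± 48.7 to 1419 ± 843 CPM), *Camp* (4.33 ± 0.76, from 6.18 ± 6.04 to 127 ± 75.0 CPM), *Ngp* (4.13 ± 0.68) and *Fcnb* (3.23 ± 0.86) rose (n = 10 and 7), with 7 of 15 members of the list (8 adjusted over the list alone, camera adjusted p = 1.97e-05, adjusted p = 0.441 with an estimated correlation). Genes of the mature neutrophil fell in 6 of 15 cases (7 fell and 1 rose adjusted over the list alone), among them the gelatinase gene *Mmp9* (-0.61 ± 0.17) and the histone-modifying enzyme gene *Padi4* (-0.66 ± 0.18) (camera adjusted p = 0.00139, adjusted p = 0.441 with an estimated correlation). Chemoattractant and adhesion receptors fell in 4 of 16 (6 adjusted over the list alone), with *Itgal* (-0.67 ± 0.11), whereas *Cxcr1* (1.21 ± 0.27) rose (camera adjusted p = 0.00438, adjusted p = 0.441 with an estimated correlation). *Cxcr2* stood at -0.19 ± 0.14 (adjusted p = 0.392). Ribosomal protein genes rose in 4 of 20, with *Rpl13* (1.33 ± 0.36) and *Rpl5* (1.20 ± 0.27) (camera adjusted p = 0.000783, adjusted p = 0.463 with an estimated correlation). *Nos2* (5.75 ± 1.43), the endothelial lipase gene *Lipg* (5.64 ± 1.29) and the complement gene *C4b* (4.93 ± 0.72) rose, and *Sema7a* (-2.01 ± 0.28) and the chemokine gene *Ccl6* (-0.96 ± 0.25) fell. In all 1527 of 10217 genes changed, 671 upward and 856 downward. Within run set A 993 genes changed, and *Ltf* stood at 4.61. Without the untreated libraries labelled Vehicle 789 changed, and 973 did with no filter on low counts.

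CXCR2i alone moved 705 blood neutrophil genes, 312 upward and 393 downward (n = 10 and 7). *Camp* (3.66 ± 0.88, from 6.18 ± 6.04 to 81.9 ± 74.3 CPM), *Ltf* (3.43 ± 0.88, from 56.6 ± 48.7 to 755 ± 607 CPM), *Ngp* (3.17 ± 0.78) and *Lipg* (5.37 ± 1.61) rose, and 3 of 15 specific granule genes passed (4 adjusted over the list alone, camera adjusted p = 0.0456, adjusted p = 0.864 with an estimated correlation). Interferon-stimulated genes fell in 3 of 17 cases (7 adjusted over the list alone), *Rsad2* (-1.93 ± 0.40), *Isg15* (-1.08 ± 0.33) and *Irf7* (-0.99 ± 0.31) (camera adjusted p = 1.38e-06, adjusted p = 0.49 with an estimated correlation). The count was 1770 with no filter, 1185 without the run term and 91 without the libraries labelled Vehicle or isotype. It was 1273 without untreated replicate 6 and 165 without CXCR2i replicate 1, the only one of run set A.

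With aPD1 alone no blood neutrophil gene passed by edgeR (n = 5 and 7). At an unadjusted p under 0.05 there were 779 genes, and 5 passed by DESeq2. The B cell gene *Ms4a1* stood at 5.81 ± 1.57 and *Nos2* at 5.46 ± 1.94 (adjusted p = 0.542 each). B cell markers rose in 3 of 4 adjusted over the list alone and in 0 over all genes. The B cell gene *Cd79a* was at 20.4 CPM in aPD1 replicate 5 and 0.125 to 0.634 in the others.

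The combination's effects on liver and blood neutrophils were compared as an interaction within animals (n = 8 and 6). Some granule and maturation genes rose more in liver. *Cebpe* (3.37 ± 0.56), *Cd177* (3.04 ± 0.65), *Mmp8* (2.45 ± 0.60), *Retnlg* (2.25 ± 0.61) and *Cybb* (1.88 ± 0.49) passed, as did 4 of 15 specific granule genes (9 adjusted over the list alone, camera adjusted p = 1.99e-11, adjusted p = 0.406 with an estimated correlation). *C4b* (-4.66 ± 0.93) and the B cell gene *Cr2* (-5.98 ± 1.47) moved the other way. T and NK cell markers had a median difference of -5.12 and B cell markers one of -4.32, with 6 and 5 members lower when adjusted over the list alone. In all 312 genes differed, 217 upward and 95 downward, with a median of -0.183 over all genes. The split was 489 to 420 by DESeq2, and the count was 578 with no filter and 202 without the shallow or mixed libraries. Without untreated liver and blood of liver replicates 2, 3 and 4 in turn the count was 146, 192 and 184. It was 205 without CXCR2i and aPD1 liver and blood of liver replicate 3.

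Liver and blood T cells of the same untreated animals came next. Liver T cells expressed effector, checkpoint and activation genes at higher levels. *Pdcd1* (2.40 ± 0.27, from 26.2 ± 10.8 to 137 ± 56.2 CPM), on chromosome 1 from 94038305 to 94052553, *Ctla4* (2.11 ± 0.33), *Havcr2* (2.62 ± 0.25) and the co-stimulatory receptor gene *Tnfrsf9* (3.13 ± 0.31) rose, with 15 of 15 checkpoint genes (15 adjusted over the list alone, camera adjusted p = 8.95e-12, and 0.044 with an estimated correlation). The cytokine genes *Il10* (5.66 ± 0.40), *Ifng* (3.48 ± 0.30), *Il21* (3.76 ± 0.47) and *Ccl3* (4.48 ± 0.29) rose, and cytotoxic and type 1 effector genes rose in 16 of 20 cases (16 adjusted over the list alone, camera adjusted p = 6.79e-07, adjusted p = 0.099 with an estimated correlation). Tissue residency genes rose in 9 of 12 (9 adjusted over the list alone), led by *Rgs1* (3.53 ± 0.30) (camera adjusted p = 1.94e-06, and 0.044 with an estimated correlation). Immediate early and heat shock genes, which also rise when tissue is dissociated, rose in 15 of 15 (15 adjusted over the list alone), with *Hspa1a* (7.01 ± 0.50) (camera adjusted p = 1.5e-11, and 0.044 with an estimated correlation). Cell cycle genes rose in 28 of 30 (29 adjusted over the list alone, camera adjusted p = 1.32e-15, adjusted p = 0.099 with an estimated correlation). Naive and central memory genes fell in 12 of 13 (12 adjusted over the list alone), with the lymph node homing receptor gene *Ccr7* (-2.14 ± 0.31) and *Igfbp4* (-2.33 ± 0.48) (camera adjusted p = 1.31e-09, adjusted p = 0.099 with an estimated correlation).

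All 11 measured hepatocyte markers rose too (11 adjusted over the list alone, camera adjusted p = 0.000417, adjusted p = 0.343 with an estimated correlation). *Alb* went from 0.852 ± 0.844 to 103 ± 139.7 CPM. Monocyte and macrophage markers rose in 11 of 14 (11 adjusted over the list alone), with *C1qa* (8.13 ± 0.99) (camera adjusted p = 8.28e-05, adjusted p = 0.24 with an estimated correlation), and the platelet genes *Ppbp* (-4.93 ± 0.81) and *Pf4* (-2.79 ± 0.84) fell. In all 5520 of 13430 genes changed, 2996 upward and 2524 downward (n = 6 and 6).

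**Figure D3:**
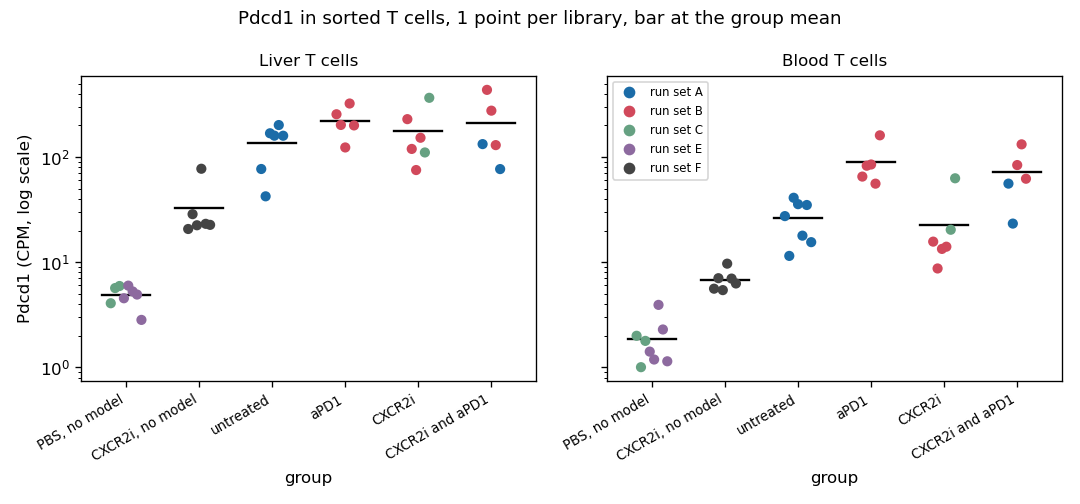
*Pdcd1* CPM per library (of gene counts, log axis) in T cells of liver and blood by group, with colour for the run set and a bar at the group mean. The libraries of untreated DEN ALIOS mice ran from 42.3 to 201 CPM in liver and from 11.5 to 41.0 CPM in blood, and those of PBS mice from 2.83 to 5.98 and from 1.00 to 3.92 CPM.

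The T cell treatments were compared. Against CXCR2i alone, liver T cells of the combination group held more transcripts of some cytotoxic and checkpoint genes. The granzyme genes *Gzma* (2.43 ± 0.56, from 151 ± 210 to 274 ± 95.3 CPM) and *Gzmb* (2.00 ± 0.51, from 265 ± 191 to 511 ± 206 CPM), the chemokine gene *Ccl5* (1.92 ± 0.39), *Cd8a* (1.37 ± 0.37) and *Adgrg1* (2.53 ± 0.54) rose, with 6 of 20 cytotoxic genes (9 adjusted over the list alone, camera adjusted p = 1.59e-05, adjusted p = 0.575 with an estimated correlation). The inhibitory receptor gene *Lag3* (2.66 ± 0.61), *Tox* (1.21 ± 0.32) and *Tox2* (1.79 ± 0.45), which are linked to exhaustion, rose with 3 of 15 checkpoint genes (8 adjusted over the list alone, camera adjusted p = 1.59e-05, adjusted p = 0.575 with an estimated correlation), and *Il10* (2.63 ± 0.66) rose. Innate-like T cell genes had a median of -2.35, and 9 of 14 fell when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000433, adjusted p = 0.575 with an estimated correlation). The largest falls, *Chad* (-5.23 ± 1.27), *Jcad* (-3.33 ± 0.84), *Klf4* (-3.30 ± 0.70) and *Dkk3* (-3.08 ± 0.70), stand beside endothelial markers, of which 6 of 6 fell when adjusted over the list alone. In all 448 genes changed, 195 upward and 253 downward, resting on run set B (n = 3 of 5 and 4 of 6). The count was 42 in a fit of run set B alone, 992 by DESeq2, 0 without the run term and 5 without CXCR2i and aPD1 replicate 3.

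Against untreated mice, liver T cells given CXCR2i changed in 87 genes, 66 upward and 21 downward (n = 6 and 6). *Nebl* (3.43 ± 0.68), *Emp1* (2.85 ± 0.53) and the oxysterol receptor gene *Gpr183* (2.16 ± 0.40) rose, and *Art2b* (-2.14 ± 0.37) and *Ifi27* (-1.29 ± 0.24) fell. Innate-like genes had a median of 2.50 (camera adjusted p = 0.000961, adjusted p = 0.555 with an estimated correlation), with *Il17a* at 5.31 ± 1.55 (adjusted p = 0.0796), not passing over all genes, and 4 of 14 list members rising when adjusted over the list alone. Cytotoxic genes had a median of -0.91, and 8 of 20 fell when adjusted over the list alone (camera adjusted p = 0.000634, adjusted p = 0.555 with an estimated correlation). The groups shared no run set, so the fold changes rest on the combination libraries that link the run sets. DESeq2 gave 502 up and 270 down, and the count was 986 without the run term and 1 without the libraries labelled Vehicle. CXCR2i replicate 3 held neutrophil and hepatocyte transcripts. Without untreated replicates 2, 3, 4 and 5 in turn the count was 202, 6, 16 and 6. It was 334 and 12 without CXCR2i replicates 3 and 4 in turn.

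The combination against no treatment moved 22 liver T cell genes, 15 upward and 7 downward (n = 5 and 6), among them the secretory pathway genes *Sdf2l1* (-1.14 ± 0.19) and *Canx* (-0.56 ± 0.11) and the respiratory chain gene *Uqcr10* (-0.78 ± 0.15), which fell, and *Atp8a2* (2.02 ± 0.37) and *Lncpint* (1.18 ± 0.21), which rose. With the run set term, the fold changes rest on run set A, which held 2 of the combination and all 6 untreated libraries. *Pdcd1* stood at -0.38 ± 0.54 (adjusted p = 0.772), and without the run term it stood at 0.56 and *Sdf2l1* at 0.081. Cell cycle genes had a median of -0.55 with no member passing (camera adjusted p = 1.15e-06, adjusted p = 0.877 with an estimated correlation). DESeq2 gave 248 up and 214 down, and the count was 0 without the run term, 0 with no filter and 22 within run set A, 8 of them shared. Without untreated replicates 1 to 6 in turn the count was 0, 98, 4, 5, 5 and 133. It was 0, 6, 5, 11 and 0 without CXCR2i and aPD1 replicates 1, 2, 3, 4 and 5 in turn.

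With aPD1 alone 1 liver T cell gene passed against no treatment, the secretory pathway gene *Sdf2l1* (-1.57 ± 0.24, adjusted p = 0.0365), at 15.1 ± 2.94 against 13.9 ± 1.09 CPM, and 53 passed by DESeq2 (n = 5 and 6). *Pdcd1*, the gene of the antibody's target, stood at -0.72 ± 0.72 (adjusted p = 0.729), at 210.1 ± 68.6 against 137 ± 56.4 CPM. These fold changes rest on the combination libraries that link the run sets, and without the run term *Sdf2l1* stood at 0.12, *Pdcd1* at 0.62 and 8 genes passed. Without any of untreated replicates 1 to 6 the count was 0. It was 2, 0 and 0 without aPD1 replicates 2, 3 and 5 in turn. In the combination against aPD1 alone 0 liver T cell genes passed by edgeR, 364 had an unadjusted p under 0.05 and 1 passed by DESeq2 (n = 3 and 5 in run set B). Innate-like genes there had a median of 1.48, with 6 of 14 rising when adjusted over the list alone (camera adjusted p = 6.35e-06, adjusted p = 0.173 with an estimated correlation).

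In blood T cells of the combination group platelet and monocyte genes rose, which rested on 2 of 5 libraries. The platelet chemokine gene *Pf4* (2.85 ± 0.64, from 3.93 ± 2.42 to 11.5 ± 14.7 CPM), *Ppbp* (2.63 ± 0.68), *Thbs1* (3.16 ± 0.69) and the monocyte gene *F13a1* (2.75 ± 0.68) rose (n = 5 and 7), with 3 of 11 erythroid and platelet markers (5 adjusted over the list alone, camera adjusted p = 9.57e-06, adjusted p = 0.386 with an estimated correlation) and 2 of 8 monocyte markers (5 adjusted over the list alone, camera adjusted p = 0.000489, adjusted p = 0.386 with an estimated correlation). *Pf4* was at 23.0 and 31.1 CPM in combination replicates 1 and 2, of run set A, which held *Hbb-bs* at 3457 and 7357 CPM, and from 0.432 to 2.00 CPM in the others. Leaving out either, none of these 4 genes passed. Among T cell genes the activating receptor gene *Klrk1* (0.72 ± 0.16) and the glucose transporter gene *Slc2a3* (0.59 ± 0.11) rose, and the gut homing receptor gene *Ccr9* (-1.29 ± 0.28) and *Art2b* (-1.26 ± 0.26) fell. Interferon-stimulated genes fell in 1 of 20 cases (9 adjusted over the list alone, camera adjusted p = 5.84e-05, adjusted p = 0.386 with an estimated correlation). *Pdcd1* stood at 0.47 ± 0.49 (adjusted p = 0.727). In all 313 genes changed, 265 upward and 48 downward, resting on run set A (2 and 7 libraries). The count was 83 within run set A and 562 without the run term, and the split by DESeq2 was 301 to 136. Without untreated replicate 5 the count was 198. It was 134 and 202 without CXCR2i and aPD1 replicates 1 and 2 in turn.

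CXCR2i alone moved 54 blood T cell genes, 46 upward and 8 downward (n = 6 and 7). B cell genes rose, *Ms4a1* (3.36 ± 0.73) and *Cd79b* (1.94 ± 0.43), with 2 of 9 list members (6 adjusted over the list alone, camera adjusted p = 2.62e-07, adjusted p = 0.254 with an estimated correlation). *Klrk1* (1.20 ± 0.23) and *Anxa1* (2.23 ± 0.49) rose, and *Cd8a* (-0.78 ± 0.17) and *Art2b* (-1.53 ± 0.34) fell. Checkpoint genes had a median of -1.05 (camera adjusted p = 6.86e-06, adjusted p = 0.254 with an estimated correlation), with *Pdcd1* at -2.29 ± 0.72 (adjusted p = 0.194) and *Lag3* at -3.44 ± 1.01 (adjusted p = 0.163). The counts up and down were 117 and 57 by DESeq2, and the count was 356 without the run term and 5 without the libraries labelled Vehicle. Without untreated replicates 2, 3 and 4 in turn the count was 86, 34 and 19. It was 13 and 32 without CXCR2i replicates 2 and 4 in turn. With aPD1 alone 2 genes passed, *Grina* (1.35 ± 0.20, adjusted p = 0.00877) and the platelet integrin gene *Itgb3* (1.22 ± 0.19, adjusted p = 0.00973), against 42 by DESeq2 and 1334 without the run term (n = 5 and 7). *Itgb3* was at 62.7 ± 9.66 CPM with aPD1 and 79.4 ± 10.8 without, so its direction rests on the run term, and without that term it stood at -0.34 and *Grina* at -0.084. Without untreated replicates 1, 2 and 3 in turn the count was 4, 6 and 4.

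The same interaction as in neutrophils was tested in T cells within animals (n = 5 and 6). No gene passed by edgeR, 947 had an unadjusted p under 0.05, and 0 passed by DESeq2. *Pdcd1* differed by -0.89 ± 0.38 (adjusted p = 0.682) and *Lag3* by -1.03 ± 0.43 (adjusted p = 0.682). Cell cycle genes had a median difference of -0.73 (camera adjusted p = 1.43e-12, adjusted p = 0.448 with an estimated correlation).

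T cells of untreated DEN ALIOS mice were compared with those of PBS mice, which carry no DEN ALIOS label. The diet of the PBS mice is not given in the sources used here, so the carcinogen and the diet cannot be told apart. In liver, checkpoint, effector and proliferation genes were higher in DEN ALIOS mice. *Pdcd1* (4.55 ± 0.37, from 5.54 ± 1.61 to 122 ± 49.9 CPM), *Lag3* (5.70 ± 0.46), *Ctla4* (2.84 ± 0.38) and *Tox2* (4.87 ± 0.48) rose, with 14 of 15 checkpoint genes (14 adjusted over the list alone, camera adjusted p = 1.26e-13, and 0.0334 with an estimated correlation). *Gzmk* (5.58 ± 0.42), *Ccl3* (5.93 ± 0.62) and *Il10* (6.93 ± 0.67) rose, as did 13 of 20 cytotoxic genes (14 adjusted over the list alone, camera adjusted p = 2.79e-08, adjusted p = 0.0611 with an estimated correlation) and 25 of 30 cell cycle genes (27 adjusted over the list alone, camera adjusted p = 2.59e-10, adjusted p = 0.114 with an estimated correlation). *Cd8a* (1.48 ± 0.22) rose, and the NK and NKT cell genes *Klrb1c* (-3.72 ± 0.48), *Zbtb16* (-3.87 ± 0.49) and *Il4* (-3.99 ± 0.79) fell. Naive genes fell in 10 of 13 (10 adjusted over the list alone, camera adjusted p = 5.86e-10, adjusted p = 0.114 with an estimated correlation). Haemoglobin, *Hbb-bs* (9.36 ± 1.19, from 2.13 ± 3.74 to 887 ± 1259 CPM), and macrophage genes such as *C1qc* (4.17 ± 0.88) also rose. Of PBS replicates 3 and 4, 90.9 and 89.8% of entries were unaligned. In all 3936 genes changed, 1944 upward and 1992 downward (n = 6 and 8). The groups shared no run set, and with the treated groups added to link the run sets 2216 genes changed.

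In blood the same contrast gave *Pdcd1* (3.81 ± 0.28, from 1.81 ± 0.899 to 26.9 ± 10.8 CPM), *Lag3* (4.16 ± 0.32), *Gzmk* (4.27 ± 0.42) and *Ccl3* (5.47 ± 0.45) as rising genes, with 13 of 15 checkpoint genes (13 adjusted over the list alone, camera adjusted p = 3.67e-16, and 0.0033 with an estimated correlation) and 17 of 20 cytotoxic genes (18 adjusted over the list alone, camera adjusted p = 3.59e-18, and 0.0152 with an estimated correlation). B cell markers fell in 9 of 9 (9 adjusted over the list alone), with *Cr2* (-3.39 ± 0.34) and *Ms4a1* (-2.91 ± 0.29) (camera adjusted p = 3.68e-12, and 0.0373 with an estimated correlation), and erythroid genes such as *Hbb-bs* (4.83 ± 0.79) rose, 10 of 10 in that list (10 adjusted over the list alone, camera adjusted p = 3.44e-08, adjusted p = 0.12 with an estimated correlation). In all 2815 genes changed, 1509 upward and 1306 downward (n = 7 and 8), and 526 did with the treated groups added to link the run sets, where *Hbb-bs* stood at -0.14.

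CXCR2i without the tumour model was compared with PBS. In liver T cells interleukin 17 and other innate-like genes were higher. *Il17a* (9.04 ± 0.91, from 0.0761 ± 0.215 to 24.7 ± 4.92 CPM), on chromosome 1 from 20730905 to 20734496, *Il23r* (4.80 ± 0.56) and *Sox13* (4.75 ± 0.53) rose, with 7 of 14 innate-like genes (8 adjusted over the list alone, camera adjusted p = 6.76e-05, adjusted p = 0.101 with an estimated correlation). *Pdcd1* (2.54 ± 0.37), *Lag3* (2.84 ± 0.46) and *Rgs1* (2.62 ± 0.23) rose, with 9 of 15 checkpoint genes (10 adjusted over the list alone, camera adjusted p = 1.07e-05, adjusted p = 0.101 with an estimated correlation). Hepatocyte genes fell in 8 of 10 (9 adjusted over the list alone), with *Alb* (-6.75 ± 1.58, from 344 ± 591 to 2.96 ± 1.77 CPM) (camera adjusted p = 3.46e-07, adjusted p = 0.169 with an estimated correlation). In all 2177 genes changed, 994 upward and 1183 downward (n = 6 and 8), and 1378 did against the PBS libraries of run set E alone. In blood, *Il23r* (3.32 ± 0.40), *Il1r1* (4.09 ± 0.46), *Ifng* (2.58 ± 0.35) and *Pdcd1* (1.82 ± 0.33) rose, and cytotoxic genes rose in 13 of 20 (15 adjusted over the list alone, camera adjusted p = 5e-12, and 0.0409 with an estimated correlation). The largest rises were of the apolipoprotein genes *Apoa4* (8.13 ± 0.41, from 0.0348 ± 0.0656 to 14.7 ± 3.97 CPM), on chromosome 9 from 46240696 to 46243459, and *Apob* (6.08 ± 0.55), beside markers of intestinal epithelium such as *Sis* (5.66 against 0.0119 CPM), *Vil1* (4.08 against 0.127) and *Krt20* (3.05 against 0). In all 1389 genes changed, 845 upward and 544 downward. All CXCR2i libraries of these groups came from run set F and no PBS library did, so the group and the run cannot be told apart.

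Camera list tests were called in 250 of the list tests with the preset correlation and in 17 with an estimated one. Those that held were the specific granule genes in liver neutrophils of the combination against aPD1, the checkpoint, residency, inflammatory and immediate early lists in T cells of liver against blood, and the checkpoint list in liver T cells of DEN ALIOS against PBS mice. In blood T cells against PBS, the checkpoint, cytotoxic, residency, naive and B cell calls held for DEN ALIOS mice, and the cytotoxic, naive, regulatory, residency, innate-like and glycolysis calls for CXCR2i alone. For 2 called lists the signs differed. Pericentral genes had a median of 0.075 and a mean of -0.12 in large against small tumours and were called lower (camera adjusted p = 0.0048, adjusted p = 0.751 with an estimated correlation). Hepatocyte markers had a median of -0.90 and a mean of -0.65 in the T cell test of liver against blood effects and were called higher (camera adjusted p = 0.0429, adjusted p = 0.723 with an estimated correlation).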

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

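The tests of the granule and B cell patterns and the splits within run sets were chosen only after those results were seen, and the tests of the apolipoprotein pattern and of splits across run sets before. Neutrophils of mice given CXCR2i and aPD1 held more specific granule transcripts, with a median log2 fold change of 3.06 in liver and 1.19 in blood. Liver *Ltf* was also high with CXCR2i alone, at 6820 CPM against 11070 with both, 408 with aPD1 and 345 untreated. The tables argue against the sequencing run as the whole cause, since the median within run set A was 3.01 in liver and 1.19 in blood, and against shallow or mixed libraries, without which it was 2.9 in liver. Less RNA from other cells would raise all neutrophil genes, but the medians of granule and mature neutrophil genes in liver lay 3.27 apart, the latter at -0.21. A larger share of immature neutrophils may underlie the pattern, a hypothesis for which 7 of 15 mature neutrophil genes fell in blood and 1 rose, adjusted over the list alone. Whether transcript levels changed within cells of 1 stage was not tested.

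B cell transcripts were the lymphocyte genes that set untreated liver neutrophils furthest from those given CXCR2i and aPD1, with a median log2 fold change of -4.78 over 9 genes. The Ly6G sort should remove B cells, 2 of the 9 genes reached 1 CPM in untreated blood neutrophils, and *Ighm* was the most abundant at 116 CPM in untreated and 92.3 in combination libraries. A lower share of neutrophils in general would raise other cells' markers alike, but the medians of B cell, T and NK cell, hepatocyte and endothelial lists spanned 3.18, and the upper quartile of B cell genes (-4.31) lay below the lower quartile of hepatocyte genes (-1.89). Single libraries and the run set may each account for part, since the median was -2.34 without the shallow or mixed libraries and -2.29 within run set A. RNA of B cells carried through the sort, and a treatment effect on B cells in the liver, both stay open.

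T cells given CXCR2i without the tumour model held apolipoprotein transcripts in blood, *Apoa4* at 14.9 ± 4.19 CPM and *Apob* at 11.7 ± 3.23 CPM (n = 6), against 0.161 CPM of *Apob* with PBS. Hepatocytes are excluded as the source, since *Alb* over *Apoa4* was 0.0215 there and 38.7 in liver tissue. RNA of intestinal epithelium, which a CD3 sort should exclude, is a candidate source: 13 of 15 of its marker genes reached 1 CPM in blood, led by *Lgals4* (12.9 CPM, and 8.3 with PBS), *Epcam* (6.48 and 1.28) and the sucrase gene *Sis* (5.66 and 0.0119), against 2 with PBS and 4 in liver tissue. Of the 12 libraries only liver replicate 4 held no *Apoa4* count, while blood of replicate 4 held 96. The run set held 0 libraries of other groups, so run and group cannot be told apart, and an effect of the inhibitor stays open as untested.

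Single libraries stood far from the others of their group in 17 of 60 tests, each of a group and a measure. The gap to the nearest library over the range was used. Chance gives 1 in 20 only for normally distributed values, so no excess is shown. For gene counts these were untreated blood neutrophil replicate 1 (950500, the others from 6013000) and untreated blood T cell replicate 7 (10580000, the others up to 6714000). *Ltf* stood out in blood neutrophils given aPD1, replicate 2, at 198 CPM. *Alb* stood out in blood neutrophils of untreated replicate 7 (9.62 CPM), aPD1 replicate 5 (3.85) and CXCR2i replicate 9 (28.5) and in liver neutrophils of CXCR2i replicate 7 (346) and combination replicate 7 (268). In T cells *Alb* did so in blood of CXCR2i replicate 6 (3.16 CPM) and in liver of CXCR2i replicate 3 (934) and combination replicate 3 (2192). *Apoa4* did so in those liver libraries (68.3 and 288 CPM), in liver of untreated replicate 2 (146) and aPD1 replicate 3 (40.7) and in blood of CXCR2i replicate 2 (2.51) and combination replicate 4 (2.16).

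The combination's effect differed between liver and blood neutrophils in 312 genes by the interaction test. Among reads outside the gene counts, those that HTSeq could not give to a single gene were more frequent in tumours, at 2.57 ± 0.433% in large (n = 25) and 2.49 ± 0.342% in small ones (n = 25), against 1.33 ± 0.224% in liver tissue (n = 15, two-sided permutation p = 1e-05 for each, the smallest the permutations can give). Within the 3 runs the difference was 1.03, 1.49 and 1.2 percentage points for large and 1.08, 1.32 and 1.23 for small tumours. Reads aligned at several places were less frequent, at 47.7 ± 2.17% in large and 49.2 ± 1.88% in small tumours against 54.8 ± 3.12% (permutation p = 1e-05 for each), with differences of -6.44, -6.75 and -9.67 points within the runs for large and -4.25, -4.95 and -8.34 for small tumours.

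Splits of the libraries into groups of the same sizes, the real one included, were drawn across run sets (100 per comparison, 32 for liver against blood). Where run sets hold both groups they were drawn again with each run set's group sizes kept (100, or all possible where fewer, 28 to 56). Tissue samples that share a mouse would make these splits too lenient. Chance was unlikely in 11 of 27 comparisons (at most 1 split in 32 as large), uncorrected for their number. Within run sets 1 split, the real one, reached the real count in the following, given as that count, the highest other within run sets and the highest across them: 10253, 5435 and 6332 in large tumours, 9558, 1 and 3192 in small tumours, 360, 30 and 278 in large against small tumours, 1288, 131 and 516 in liver neutrophils given the combination, 53, 0 and 20 against aPD1, 1527, 545 and 276 in blood neutrophils given the combination, 448, 119 and 518 in liver T cells of the combination against CXCR2i, 313, 74 and 74 in blood T cells given the combination, and, in a fit of these groups alone, 274, 31 and 1 in the neutrophil interaction. Across run sets 2 splits reached the count of the combination against CXCR2i, and 1 the others. Refitted on untreated animals alone, liver against blood gave 1954 in neutrophils and 4760 in T cells (5545 and 5520 in the main fits), and the highest other was 0. Chance could not be excluded for liver T cells given the combination, where 2 of 28 splits within run sets reached the 22 genes (highest other 25, 1 across), nor where the real count was 0, which all 100 splits reach, in liver neutrophils of the combination against CXCR2i (highest other 1), liver T cells of the combination against aPD1 (4) and the T cell interaction (71). Splits that keep run sets are too few where groups share none, or 1 with a single treated library. With the real count, splits as large and the highest other across run sets, these are liver T cells given aPD1 (1, 2, 40) and CXCR2i (87, 4, 149), blood T cells given aPD1 (2, 3, 137) and CXCR2i (54, 1, 0), neutrophils given aPD1 in liver (0, 100, 1654) and blood (0, 100, 27) and CXCR2i in liver (17, 2, 139) and blood (705, 2, 1116), and, against PBS, T cells of CXCR2i alone in liver (2177, 1, 436) and blood (1389, 1, 329) and of DEN ALIOS mice in liver (3936, 1, 3306) and blood (2815, 1, 1279). Single splits called several times the real count for neutrophils and T cells given aPD1, liver neutrophils given CXCR2i and the T cell interaction. The cause was not tested.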

How the results depend on the processing

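Alternatives were fixed before the data were examined, except leaving out the shallow or mixed libraries and the tissue libraries over 10 CPM of *S100a8*, which was chosen after the data were seen. Of 27 gene counts, 25 stayed within 1.5 times the main count with RLE factors, 18 with no filter on low counts and 13 with DESeq2. The 272 named gene values had 4470 values under alternatives, of which 3810 kept direction and side of the threshold, 642 no longer passed, 10 newly passed and 8 turned. What limits recovery (depth, group size or spread) was not tested. On the simulated counts, 3% of 2-fold and 56% of 4-fold changes were recovered in liver neutrophils given the combination, and 70% and 92% in blood T cells. For the changes below the cause was not tested, except where fewer libraries, fewer genes or a stricter threshold enter by construction.

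Counts past 1.5 times the main count are listed by setting, against untreated mice or liver tissue unless named. With a change of at least 2-fold required they were 2587 in large tumours, 2091 in small tumours, 91 in large against small tumours, 287 in blood neutrophils CXCR2i, 454 in blood neutrophils combination, 42 in liver T cells CXCR2i, 6 in liver T cells combination, 199 in liver T cells combination against CXCR2i, 32 in blood T cells CXCR2i, 177 in blood T cells combination, 1918 in T cells of liver against blood, 1036 in liver T cells CXCR2i against PBS, 1665 in liver T cells DEN ALIOS against PBS, 347 in blood T cells CXCR2i against PBS and 573 in blood T cells DEN ALIOS against PBS. With no filter they were 29 in liver neutrophils CXCR2i, 31 in liver neutrophils combination against aPD1, 1770 in blood neutrophils CXCR2i, 973 in blood neutrophils combination, 0 in liver T cells aPD1, 9 in liver T cells CXCR2i, 0 in liver T cells combination, 227 in liver T cells combination against CXCR2i and 578 in the neutrophil interaction. With DESeq2 they were 565 in large against small tumours, 326 in liver neutrophils CXCR2i, 2176 in liver neutrophils combination, 153 in liver neutrophils combination against aPD1, 1 in liver neutrophils combination against CXCR2i, 5 in blood neutrophils aPD1, 53 in liver T cells aPD1, 772 in liver T cells CXCR2i, 462 in liver T cells combination, 1 in liver T cells combination against aPD1, 992 in liver T cells combination against CXCR2i, 42 in blood T cells aPD1, 174 in blood T cells CXCR2i and 909 in the neutrophil interaction. With RLE factors they were 24 in liver neutrophils combination against aPD1 and 149 in liver T cells CXCR2i. Without the run term they were 38 in liver neutrophils aPD1, 645 in liver neutrophils CXCR2i, 654 in liver neutrophils combination against aPD1, 8 in blood neutrophils aPD1, 1185 in blood neutrophils CXCR2i, 8 in liver T cells aPD1, 986 in liver T cells CXCR2i, 0 in liver T cells combination, 0 in liver T cells combination against CXCR2i, 1334 in blood T cells aPD1, 356 in blood T cells CXCR2i and 562 in blood T cells combination. With each run as its own term in place of run sets they were 0 in liver neutrophils combination against aPD1, 12 in liver T cells combination and 9 in blood T cells aPD1. Without the libraries labelled Vehicle or isotype they were 1 in liver neutrophils CXCR2i, 0 in liver neutrophils combination against aPD1, 91 in blood neutrophils CXCR2i, 789 in blood neutrophils combination, 0 in liver T cells aPD1, 1 in liver T cells CXCR2i, 0 in liver T cells combination, 5 in blood T cells CXCR2i and 199 in blood T cells combination. In run sets A and B they were 43 in liver neutrophils CXCR2i and 50 in liver T cells CXCR2i, within run set A 307 in liver neutrophils combination, 993 in blood neutrophils combination and 83 in blood T cells combination, and within run set B 2 in liver neutrophils combination against aPD1 and 42 in liver T cells combination against CXCR2i. Without the first, the second and the third tissue run the count of large against small tumours was 15, 75 and 157, and without the tissue libraries over 10 CPM of *S100a8* 200. With PBS libraries of run set E alone it was 1378 in liver T cells CXCR2i against PBS, and with the treated groups added 2216 in liver T cells DEN ALIOS against PBS and 526 in blood T cells DEN ALIOS against PBS. Without the shallow or mixed libraries they were 2176 in liver neutrophils combination, 0 in liver neutrophils combination against aPD1, 334 in liver T cells CXCR2i, 47 in liver T cells combination, 3449 in neutrophils of liver against blood and 202 in the neutrophil interaction. Gene list calls fell from 250 to 17 with an estimated correlation, and of 158 calls in comparisons with a run term 127 were also made without it, 5 of them in the other direction.

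The title's sample number marked no shared animal between treatment groups, and in no comparison did every same-numbered pair correlate above 0.1. As a block that number gave 123 in large against small tumours, 0 in liver neutrophils CXCR2i, 736 in liver neutrophils combination, 0 in liver neutrophils combination against aPD1, 0 in liver T cells aPD1, 0 in liver T cells CXCR2i, 0 in liver T cells combination, 216 in liver T cells combination against CXCR2i, 0 in blood T cells aPD1, 0 in blood T cells CXCR2i and 40 in blood T cells combination, and moved no other count past 1.5 times. Liver and blood libraries of 1 animal were a block of the main fits, and without that block 6187, 403, 5191 and 0 genes passed for neutrophils of liver against blood, their interaction, T cells of liver against blood and their interaction.

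Leaving out 1 library or animal gave 0 to 91 in liver neutrophils CXCR2i, 759 to 1488 in liver neutrophils combination, 0 to 55 in liver neutrophils combination against aPD1, 0 to 1 in blood neutrophils aPD1, 165 to 1273 in blood neutrophils CXCR2i, 0 to 2 in liver T cells aPD1, 6 to 334 in liver T cells CXCR2i, 0 to 133 in liver T cells combination, 5 to 550 in liver T cells combination against CXCR2i, 2 to 6 in blood T cells aPD1, 13 to 86 in blood T cells CXCR2i, 134 to 317 in blood T cells combination, 146 to 406 in the neutrophil interaction and 0 to 1 in the T cell interaction. The values that turned were, without the run term, *Pdcd1* (0.62) and *Sdf2l1* (0.12) in liver T cells given aPD1, *Pdcd1* (0.56) and *Sdf2l1* (0.081) in those given the combination, and *Grina* (-0.084) and *Itgb3* (-0.34) in blood T cells given aPD1. With 1 library left out, *Pdcd1* in blood T cells given the combination ranged from -0.20 to 0.88, turning without combination replicate 1. With the treated groups added, *Hbb-bs* (-0.14) turned in blood T cells of DEN ALIOS against PBS mice.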

Other observations

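No test in this part was chosen only after its result was seen. In large tumours against liver tissue (n = 25 and 15), lipid synthesis genes parted. The desaturase gene *Scd2* (2.65 ± 0.27) rose, while the lipogenic regulator genes *Srebf1* (-1.47 ± 0.18) and *Thrsp* (-3.16 ± 0.35) fell, with 6 of 17 list members higher and 9 lower (camera adjusted p = 0.247). Drug-metabolizing genes were divided in the same way, 6 of 14 rising and 7 falling in large tumours (camera adjusted p = 0.0844). The 2C cytochrome genes *Cyp2c37* (-5.13 ± 0.65) and *Cyp2c50* (-4.96 ± 0.64), which share much of their sequence, fell furthest. Macrophage genes linked to recruited and lipid-laden cells rose in 8 of 12 cases in large tumours and 7 in small ones. Examples in large tumours are the lipoprotein lipase gene *Lpl* (1.58 ± 0.17), *Gpnmb* (1.65 ± 0.37) and the elastase gene *Mmp12* (1.43 ± 0.31), although the list did not pass in either (camera adjusted p = 0.0941 and 0.225). Bile duct and progenitor genes rose in 4 of 10, with *Krt23* (3.21 ± 0.37) and *Sox9* (1.96 ± 0.24), and interferon-stimulated genes were 7 up and 7 down of 21, neither list passing (camera adjusted p = 0.52 and 0.633). Adjusted over the list alone, 9 macrophage genes rose, and the counts of the other lists were as given.

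In T cells of untreated DEN ALIOS mice, glycolysis genes were higher in liver than in blood (n = 6 and 6). The hexokinase gene *Hk2* (2.096 ± 0.32), *Gapdh* (1.31 ± 0.16) and *Pgam1* (0.76 ± 0.16) rose with 12 of 19 members (13 adjusted over the list alone, camera adjusted p = 3.23e-05, adjusted p = 0.099 with an estimated correlation). Regulatory T cell genes rose in 9 of 11 cases and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 8.28e-05, adjusted p = 0.099 with an estimated correlation), and innate-like genes in 6 of 14, with *Il17a* (6.58 ± 0.88) (6 adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.24 with an estimated correlation).

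In liver T cells given CXCR2i alone the small nucleolar RNAs *Snord15a* (-6.75 ± 1.17) and *Snord42a* (-6.60 ± 1.28) were lower than with PBS (n = 6 and 8). With them fell *Rpl5* (-2.89 ± 0.56), *Rpl13* (-2.43 ± 0.54) and *Rpl13a* (-1.96 ± 0.54), while the 20 ribosomal protein genes of the list had a median of 0.015, with 1 rising and 3 falling (1 and 4 adjusted over the list alone). *Snord15a* (-6.22 ± 1.14) and *Snord42a* (-6.42 ± 1.24) also fell in DEN ALIOS against the same PBS libraries, of which replicates 1, 2, 6 and 7 held 0.98 to 2.61% ambiguous entries against 0.28 to 0.32% with CXCR2i, all from run set F.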
